A study of Mus musculus with 20 samples.

How the data were processed

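RNA from liver and brown adipose tissue of the Fob3b and F mouse lines had been compared on 2 designs of spotted cDNA array, 10 arrays each. Total RNA came from 2 pools per line and tissue. The number of animals in a pool, the labelling, scanning and background steps and any normalization are not given in the sources used here. The deposited values are 1 log2 ratio of the dyes per spot and array, and how they were made before deposition, normalization included, is not given in the sources used here. They come without intensities, and neither the log base nor the numerator is stated. The values were taken as log2 because base 10 would turn the highest of them, 7.12, into a ratio of 1.31e+07, beyond the range of a scanner. A natural logarithm is not excluded, and the fold differences given here depend on base 2. They had not been centred, since array medians ran from -0.82 to 1.40. Where a description and the channel labels of a slide differed, the channel labels were used: the brown adipose pair on the second design is described as F line against F line but has the Fob3b line in 1 channel, and the Fob3b self-self array has a description at odds with its channels.

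Each design had 17280 spots in 48 blocks of 360. Every accession paired with 2 spots, 4976 on the first design and 5129 on the second, had them 160 rows apart in 1 block, and this spacing was used to pair the spots of all 7680 clones. The 1920 control spots were left out, and no values were missing. Clone names were matched to genes with the annotation supplied for the arrays, and the reference table of assembly GRCm38.p6 served only for gene names and for which genes neighbour Sqle. On the first design 4749 clones matched 1 gene, 227 several and 2704 none, giving 3838 genes. On the second these were 4855, 274 and 2551, giving 4075 genes. Clones with several or no genes stayed in the tests of clones but were not named. The files give no coordinates.

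Each array was centred on the median of its clones, the spots of a clone were averaged, and ratios were turned so that the Fob3b line was the numerator if red is divided by green. The dye-swapped arrays of a pool pair were averaged first, so n was 2 pool pairs per tissue and design, and a p value measures the spread between pool pairs, not between animals. Clones were tested with limma 3.58.1 in R 4.3.3, with tissue as the factor, moderated variances and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was the threshold. Liver and brown adipose tissue of a design were fitted together. Liver minus brown adipose tissue was a contrast in the fit of the first design. The 1 brown adipose pool pair on the second design entered the fit but was not tested. All tests were two-sided. Self-self, between-pool and crossed-pool arrays were described without a test.

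For gene groups, clones of 1 gene were averaged, and camera of limma compared each list with all other genes at a preset correlation of 0.01. The alternative with an estimated correlation tests on the residual degrees of freedom, 2 on the first design and 1 on the second. Hardly any list could pass there, so a list that fails it is not thereby shown to be unchanged. Where the estimated correlation of a list lay above the preset, the preset can make its p too small. Of 25 lists of pathways, complexes, cell-type markers and neighbours of Sqle, 16 on the first design and 15 on the second had at least 5 measured genes and were tested, with adjustment over the lists. Adjustment over the list alone was also computed for members. The brown adipose values on the second design were ranked against 10000 random gene lists of the same size. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. That rule took, per comparison and side, the 12 genes with the largest mean among annotated clones past the threshold with the same sign on every array, filled up by smallest p with clones of the same sign that did not pass. It added Sqle, up to 4 members of each list discussed, and 10 genes per side for the comparison with 1 pool pair. Tkt, Idh1, Cyb5b and Tpm2 across designs, and Caln1, were named after their values were seen.

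Arrays differed in quality. The correlation of the paired spots of a clone ran from 0.760 to 0.932 on the first design and from 0.636 to 0.865 on the second. Printing blocks held 11.5% to 70.8% of the variance between clones on the first design and 6.05% to 40.8% on the second, and the standard deviation over clones was 0.318 to 0.631 and 0.155 to 0.302. The median SE was 0.203 for a tissue on the first design and 0.0840 on the second. Without intensities no check of signal over background was possible.

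The steps were tested on simulated data with 7680 clones. For true log2 changes of 0.5, 1 and 2, the share called was 1.49%, 55.4% and 100% for liver on the first design, 0%, 40.6% and 100% for brown adipose tissue, 0%, 0% and 75.0% for their difference, and 91.3%, 100% and 100% for liver on the second design, with 7, 5, 3 and 20 false calls. A list shifted by 0.5 was recovered by camera in liver and brown adipose tissue on the first design, with adjusted p of 5.04e-09 and 3.50e-11, and of the other 15 lists, which were not shifted, 1 also passed in liver and 0 in brown adipose tissue. The simulated clones varied independently, with 1 dye effect per clone on all arrays, closely matching paired spots and no printing-block effect. The real arrays had block effects and genes that moved together, so these shares and false calls need not hold for them.

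The alternatives were no centring, scaling of each array's spread, every array as a replicate with a dye term, a robust variance prior, clones averaged per gene, a rule of 1 sign on all arrays with 1.5-fold and no p, each tissue fitted alone, leaving out each pool pair, the pool number as a block across tissues, a fit of 4 liver RNA pools, added crossed-pool arrays, fry, camera with an estimated correlation and the first clone of each gene. Centring of each printing block and leaving out 1 liver array or either array of brown adipose pool pair 2 were added after the data had been seen.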

Results

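The data were 20 competitive hybridisations of mouse RNA on spotted cDNA arrays, made to find transcripts that differ between the F line, an obese selection line, and the Fob3b line, which carries alleles of a lean line at the Fob3b obesity locus on chromosome 15 in the F-line background. Liver and brown adipose tissue, the heat-producing fat depot, were each represented by 2 RNA pools per line. Fob3b pool 1 was hybridised against F pool 1 and Fob3b pool 2 against F pool 2, each in both dye orientations, so that n was 2 pool pairs per tissue. The first array design held 4 such arrays of liver, 4 of brown adipose tissue and 2 arrays of 1 liver pool against itself. The second held 4 of liver, 2 of brown adipose tissue from pool pair 1 alone, 2 of liver with the pools crossed between the lines, and 2 of pool 1 against pool 2 within a line. Each design carried 7680 clones, of which 4749 on the first and 4855 on the second were paired with 1 gene, and the designs shared 943 genes. The deposited values are log ratios of the dyes, read here as log2, without the intensities behind them, so the precision that can be stated is limited by the number of arrays, with 2 pool pairs per tissue. The labels do not say which dye is the numerator. A ratio on the positive side means higher RNA in the Fob3b line if red was divided by green and higher RNA in the F line if green was divided by red, so all signs given here would turn together. Ratios are relative to the median clone of each array. Every error is a moderated standard error (SE) of limma with n = 2 pool pairs per tissue unless stated. It draws the spread of a clone towards that of all clones, with 8.76 prior against 2 residual degrees of freedom for clones on the first design. It can thus lie far below the spread of the pool pairs: Deptor clone 773 in brown adipose tissue had an SD of 1.28 between them and an SE of 0.35.

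In brown adipose tissue on the first design, the question was which transcripts differed between the lines in this depot, and Deptor stood farthest from 0. Deptor encodes an mTOR-binding protein that restrains mTOR signalling and belongs to the neighbours of Sqle on chromosome 15. Its clone 773 lay on the positive side at a log2 ratio of 2.36 (SE 0.35), a 5.12-fold difference, with 3.26 in pool pair 1 and 1.46 in pool pair 2. The other Deptor clone was positive on all 4 arrays as well, and the mean of both clones was 1.72 (SE 0.25). Enzymes of lipid synthesis stood next, with Scd2, a stearoyl-CoA desaturase, at 1.20 (SE 0.25), Fdft1, the squalene synthase, at 1.01 (SE 0.22), and Me1, the malic enzyme that supplies NADPH, at 0.76 (SE 0.24). Pool pair 1 gave the larger part of these, with 1.77 against 0.64 in pool pair 2 for Scd2 and 1.23 against 0.28 for Me1, while Fdft1 had 1.15 and 0.86. In pool pair 2 the dye orientations of Fdft1 and of Scd2 differed in sign, with -0.03 and 1.76 for Fdft1 and -0.29 and 1.57 for Scd2.

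Besides both Deptor clones and Me1 clone 843, genes on the positive side on all 4 brown adipose arrays were Fam151a at 0.67, Rgs2, a regulator of G-protein signalling, at 0.56, Lss, the lanosterol synthase, at 0.54, and Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, at 0.53. Rhou and the glycogen branching enzyme gene Gbe1 had 0.47 each, as did Ctsd for the lysosomal protease cathepsin D. Npr3, the natriuretic peptide clearance receptor, had 0.44, and Pdhx of the pyruvate dehydrogenase complex and the proteasome gene Psmd7 had 0.41 each. On the negative side on all 4 arrays were Slc25a17, a peroxisomal carrier, at -0.65 and the metallothionein gene Mt2 at -0.62. Krt19, a keratin, and Gpatch2 had -0.50 each, and Actn3, an alpha-actinin of fast muscle fibres, had -0.47. Nfkbiz, the imprinted RNA H19 and Tigd5 had -0.46 each, and Cdca7 had -0.36. Rnf2 at -0.39, Lamb1 at -0.47 and Aatf at -0.40 were also negative on all arrays, but all 4 other clones of Rnf2 and the 1 other clone of Lamb1 and of Aatf had the opposite sign. The 12 named clones of the negative side lay in 8 of the 48 printing blocks, which 161 of 10000 random draws reached. The 12 of the positive side lay in 9, which 1118 draws reached. Sqle, the squalene epoxidase gene that the study singled out on these arrays, had 1.16 in pool pair 1 and -0.07 in pool pair 2, with a mean of 0.54 (SE 0.32, unadjusted limma p 0.118).

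None of these genes passed the test. With limma, 0 of 7680 clones had an adjusted p under 0.05, 65 had an unadjusted p under 0.05 (0.846%), and the smallest adjusted p was 0.283, for Deptor clone 773. With clones averaged per gene, 0 of 3838 genes passed and Deptor had an adjusted p of 0.0719. Clones with 1 sign on all 4 arrays numbered 449, or 5.85%, where 4 independent arrays would give 12.5%. The arrays were not independent: as deposited, the dye orientations correlated at 0.23 in pool pair 1 and 0.60 in pool pair 2. A positive correlation as deposited means that the arrays of a pair went against each other once turned, more so in pool pair 2. The share therefore does not measure agreement of the pool pairs. Across clones the brown adipose pool pairs correlated at -0.24, and at 0.03 with each printing block centred, so as a whole they did not agree. With brown adipose tissue fitted alone 4 clones passed, both Deptor clones, Fdft1 and Scd2, and with no centring, where the median clone of the pool pairs lay at 0.33 and 0.25, 1 passed, Deptor clone 773.

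**Figure D1:**
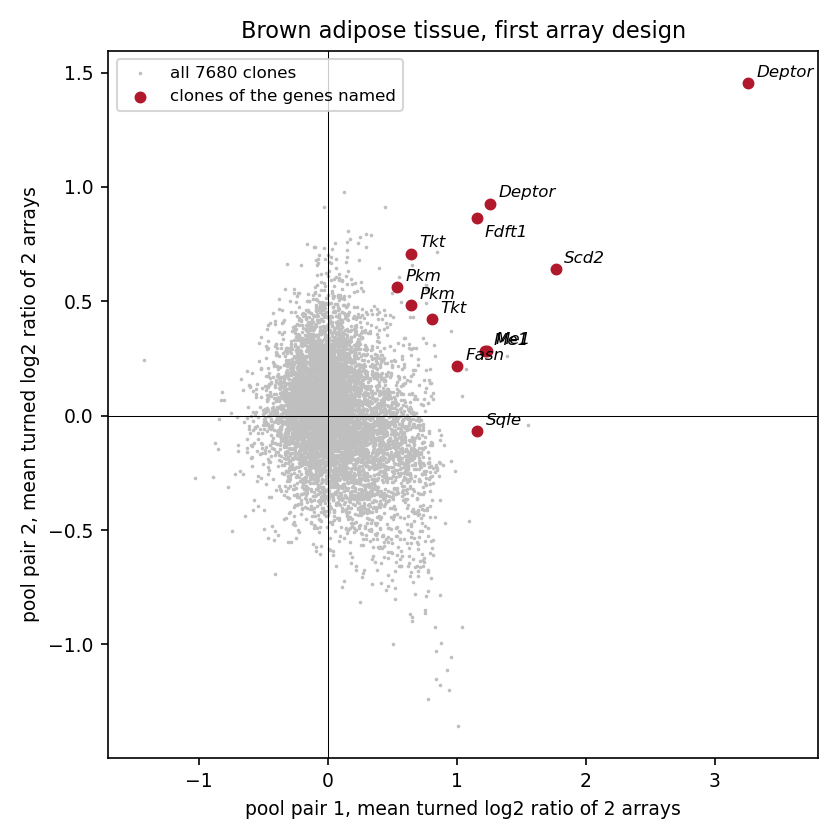
Each point is 1 clone on the first array design in brown adipose tissue, with the mean log2 ratio of the dye-swapped arrays of pool pair 1 on the x axis and of pool pair 2 on the y axis, and the clones of 8 genes in red. Deptor clone 773 lies at 3.26 and 1.46, Fdft1 at 1.15 and 0.86, and Sqle at 1.16 and -0.07.

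**Figure D2:**
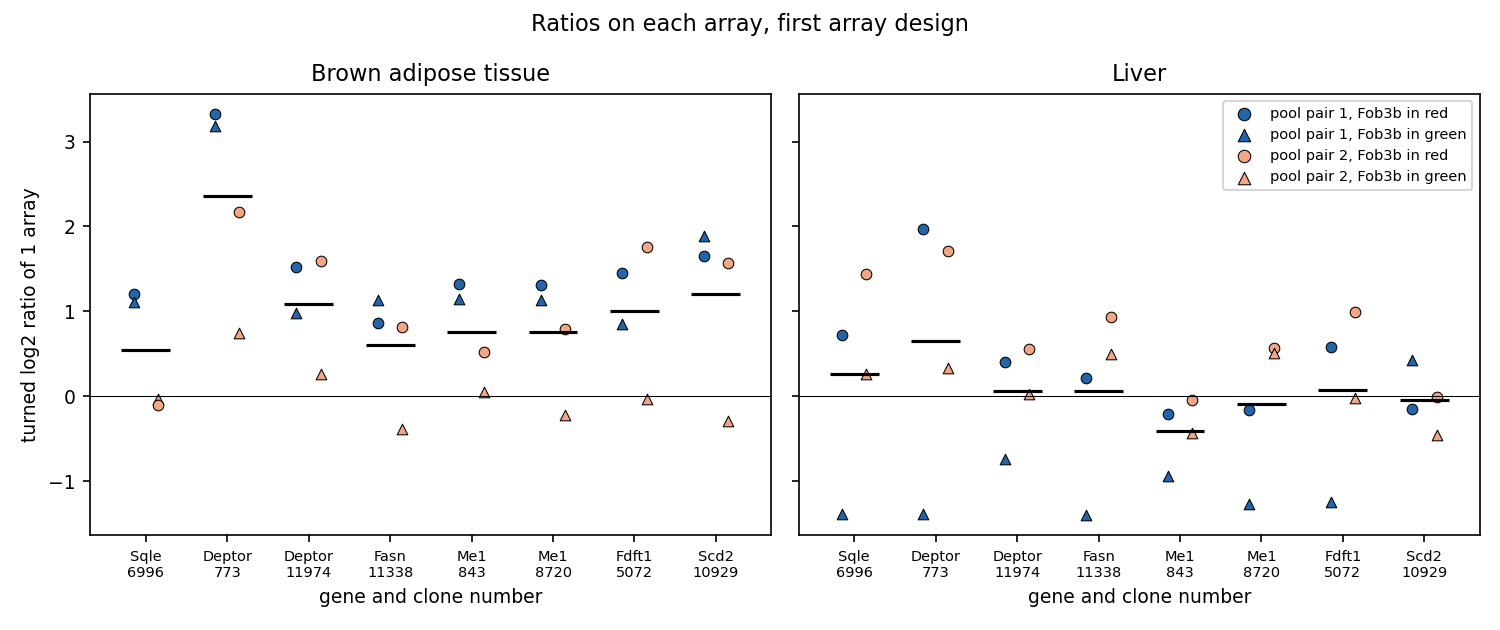
Log2 ratios of 8 clones on each of the 4 arrays per tissue on the first array design, turned so that both dye orientations read the same way, with bars at the mean of the 4 arrays. Both Deptor clones lie above 0 on all 4 brown adipose arrays, Scd2 has 1 array at -0.29, and in liver Deptor clone 773 spans -1.39 to 1.97.

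By gene group, brown adipose tissue showed enzymes of lipid, sugar and energy metabolism on the positive side. Of the 9 measured genes of fatty acid and triglyceride synthesis 8 were positive, with a median of 0.36, and besides Scd2 and Me1 these included Fasn, the fatty acid synthase, at 0.61 and the mitochondrial citrate carrier gene Slc25a1 at 0.54. All 12 measured genes of glycolysis and gluconeogenesis were positive, with a median of 0.25, among them Pkm at 0.56, Gapdh at 0.42, Pfkl at 0.39 and Pgk1 at 0.39. All 13 of the citrate cycle were positive, with a median of 0.28 and with Cs at 0.44, Mdh1 at 0.41 and Pdha1 at 0.38, as were all 18 of the respiratory chain at a median of 0.16, with Ndufa10 at 0.31 and Ndufs4 at 0.27. Of the 10 measured genes of cholesterol synthesis 7 were positive, with a median of 0.47, including Mvd at 0.46 and Dhcr7 at 0.50 beside Fdft1, Lss and Sqle. The proteasome had 17 of 18 genes on the positive side and a median of 0.12, and heat shock and protein folding had 19 of 23 and a median of 0.15, with Hspb8 at 0.55. The neighbours of Sqle on chromosome 15 had 16 of 23 positive and a median of 0.11, with Deptor at 1.72 and Vps28 at 0.57.

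These 8 groups passed camera at its preset correlation. None passed with an estimated correlation, a test on 2 residual degrees of freedom that hardly any list could pass. The adjusted p was 1.53e-06 for fatty acid and triglyceride synthesis, 8.13e-05 for glycolysis, 3.60e-07 for the citrate cycle, 0.00129 for the respiratory chain, 3.66e-04 for cholesterol synthesis, 0.00231 for the proteasome, 0.00862 for heat shock and 0.00129 for the neighbours of Sqle. With an estimated correlation the adjusted p was 0.604 for fatty acid synthesis and glycolysis and 0.633 for the other 6. That correlation ran from 0.07 for glycolysis to 0.90 for the citrate cycle, above the preset 0.01, so the preset can make p too small. Over all genes tested 0 members passed, with Scd2, Fdft1 and Deptor past 0.05 when adjusted over the list alone, at 0.00378, 0.00658 and 4.31e-04. The study named Sqle and the cholesterol and glycolysis pathways from these arrays, so the lists of cholesterol synthesis, of glycolysis and of the neighbours of Sqle are not independent evidence of a direction. The cholesterol synthesis group rested on pool pair 1, with a median of 0.72 there and 0.04 in pool pair 2 (adjusted p 0.409 without pool pair 1). In pool pair 2 the genes of the 8 groups had a median of 0.46 with the Fob3b pool in red and -0.14 with it in green, and without the array with Fob3b in red, which leaves 1 dye orientation in that pair, 0 lists passed camera. Without both arrays of pool pair 2, 5 of the 8 stayed past the threshold, and the respiratory chain, the proteasome and heat shock did not. Fatty acid oxidation had all 7 measured genes positive and a median of 0.13 but did not pass (adjusted p 0.0546), and ribosomal proteins were near even, with 15 of 29 positive. Markers of skeletal muscle lay on the negative side on the same arrays: Tpm2 at -0.58 and Actn3 at -0.47, the only measured genes of that list, both passed when adjusted over the list alone, at 0.0476 and 0.0486, and not over all genes. Hepatocyte markers had a median of -0.06 over 6 genes and macrophage markers one of 0.10 over 5, and neither passed.

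On the second design brown adipose tissue was represented by pool pair 1 alone, in both dye orientations, so its ratios are values without a test. The largest positive ratios were those of Me1 at 1.20, Alas1, the first enzyme of haem synthesis, at 1.15, Aacs, the acetoacetyl-CoA synthetase, at 1.05, Chst12 at 1.01 and Fasn at 0.98. Nudt4 had 0.89 and Msmo1, a sterol methyl oxidase, 0.86, although the other Msmo1 clone was negative. The transketolase gene Tkt had 0.84, the TGF-beta receptor gene Tgfbr2 0.82 and Ccdc3 0.81. The largest negative ratios were those of Tst, the mitochondrial thiosulfate sulfurtransferase, at -1.57, the syndecan gene Sdc4 at -1.07, the clock-linked deadenylase gene Noct at -0.92 and the cytokine-signalling inhibitor gene Cish at -0.92. Zc3h4 had -0.80, the mitophagy gene Bnip3 -0.78, Il27ra -0.77, Mtif2 -0.77, Lamb1 -0.72 and Mmp2, a matrix metalloproteinase, -0.72. The clones of Il27ra and Mmp2 have close numbers, 20920 and 20918, and an effect of printing position was not tested for them. By group, the median was 0.34 for glycolysis, 0.33 for fatty acid and triglyceride synthesis, 0.27 for the citrate cycle, 0.21 for fatty acid oxidation, 0.19 for the proteasome and 0.16 for the respiratory chain, each above at least 99.8% of 10000 random lists of as many genes. Heat shock genes had a median of 0.12, above 97.1% of random lists. The neighbours of Sqle had 0.03 and ribosomal proteins 0.03, above 53.3% and 51.5%. Random lists treat genes as independent and were not matched on transcript level. Genes of a list also moved together without a line difference, as the citrate cycle did on the first-design arrays of 1 liver pool against itself, at -0.26 and -0.18. The percentages are therefore not a test of the lines. Sqle, Deptor and Scd2 were not measured on this design. Of all clones 4764 (62.0%) kept 1 sign on both arrays, and 174 of these were past 1.5-fold, 46 positive and 128 negative.

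The RNA of brown adipose pool pair 1 was thus read by different clones on the 2 designs, and Me1, Fasn, Tkt, Idh1 and Cyb5b were past 1.5-fold on both with 1 sign. Of the 943 shared genes 49 were past 1.5-fold on the first design and 14 on the second, so most of the 49 did not reach it again. Me1 had 1.23 on the first design and 1.01 on the second as gene means, Fasn 1.0 and 0.98, Tkt 0.73 and 0.70, the isocitrate dehydrogenase gene Idh1 0.68 and 0.62, and the cytochrome b5 gene Cyb5b 0.59 and 0.64. Pool pair 2, on the first design alone, gave 0.28, 0.22, 0.57, 0.29 and 0.23 for the same genes. Tpm2, a tropomyosin of muscle, was past 1.5-fold with opposite signs, at -0.89 and 0.73. Over the 943 shared genes Pearson's r was 0.21 and Spearman's rho 0.19, and 57.4% had the same sign. These are correlations across genes, which are not independent replicates, and both designs used the same RNA.

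In liver on the second design, Fasn was the 1 annotated gene past the threshold on the positive side, at 0.63 (SE 0.08, adjusted p 0.0422), a 1.55-fold difference with 0.57 in pool pair 1 and 0.69 in pool pair 2. On the negative side 6 annotated genes passed: Snx32, a sorting nexin, at -0.67, Tanc2 at -0.62, Azin1, which spares ornithine decarboxylase, at -0.62, the kinase gene Rps6ka5 at -0.56, Lrrc26 at -0.53 and the mitochondrial import receptor gene Tomm70a at -0.51, with adjusted p from 0.0422 to 0.0471. The other Azin1 clone had the opposite sign. On the crossed-pool arrays, which held the same 4 liver pools, the 27 called clones of the negative side had a median of -0.02 against -0.59 on the direct arrays, and Fasn had 0.11. Of the 29 called clones 19 lay within 5 printing positions of another.

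Further genes with 1 sign on all 4 arrays did not pass. On the positive side these were Msmo1 at 0.78 (adjusted p 0.0895), Tmem19 at 0.64, Pip4p1 at 0.45, Mtfr1l at 0.44, Paip2 at 0.43, the innate immune kinase gene Irak1 at 0.42, A730082K24Rik at 0.41, the steroid dehydrogenase gene Hsd3b4 at 0.39, Hdhd3 at 0.39, the keratin gene Krt18 at 0.38 and the oestrogen receptor gene Esr1 at 0.36, which became -0.0012 with no centring by a shift of every clone. The 1 other clone of Mtfr1l and 1 of the 2 of Paip2 were negative. On the negative side stood Naca at -0.55, Macir at -0.54, Alas1 at -0.53, 3300002A11Rik at -0.50, Rexo4 at -0.47 and Tbc1d8 at -0.46, and both other Naca clones were positive. Alas1 and Fasn had thus -0.53 and 0.63 in liver, and 1.15 and 0.98 in brown adipose pool pair 1 on this design, a difference between tissues that was not tested here.

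In all 29 of 7680 liver clones on the second design passed with limma, 2 positive and 27 negative, and 7 of these had 1 annotated gene. At an unadjusted p under 0.05 there were 768, and 1460 clones (19.0%) had 1 sign on all 4 arrays where 4 independent arrays would give 12.5%. As deposited, the dye orientations correlated at -0.08 in pool pair 1 and -0.40 in pool pair 2. Arrays of pool pair 2 thus agreed in part once turned and those of pool pair 1 hardly did, and the share does not measure agreement of the pool pairs. With clones averaged per gene, 7 of 4075 genes passed, 1 positive and 6 negative. The count fell to 0 with the arrays scaled to a common spread, with each printing block centred and with the crossed-pool arrays added. A fit of 4 RNA pools without the pairing also gave 0. That fit took in all 8 liver arrays, crossed-pool and between-pool ones included, so its result cannot be put on the pairing alone. The count was 8 with every array as its own replicate and 159, all negative, with no centring.

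By gene group in liver on the second design, all 12 measured genes of fatty acid oxidation and ketogenesis were on the negative side with a median of -0.16, among them Cpt1a, the carnitine palmitoyltransferase of the mitochondrial outer membrane, at -0.37 (SE 0.10) and Hadha at -0.23. Enzymes of xenobiotic and glutathione metabolism were positive in 7 of 9 with a median of 0.14, and the glutathione S-transferase genes Gstm4 at 0.34, Gsta4 at 0.29 and Gstm2 at 0.26 passed when adjusted over the list alone. Ribosomal proteins had 41 of 56 positive and a median of 0.08, with Rpl24 at 0.30 and Rpl23 at 0.28, and the proteasome had 11 of 12 and a median of 0.10, with Psmd11 at 0.19. Heat shock and protein folding had 14 of 18 and a median of 0.06, although its members past 0.05 adjusted over the list alone went opposite ways, Hsp90aa1 at 0.38 and Dnaja1, a co-chaperone, at -0.36. These 5 groups passed camera, with adjusted p of 4.55e-04 for fatty acid oxidation, 9.66e-04 for xenobiotic enzymes, 7.35e-05 for ribosomal proteins, 0.00650 for the proteasome and 0.0202 for heat shock. None passed camera with an estimated correlation, on 1 residual degree of freedom (adjusted p 0.985 for each). That test decides little: xenobiotic enzymes went from 9.66e-04 to 0.985 at an estimated correlation of 0, below the preset 0.01. For the other groups the estimate lay above the preset, so the preset can make their p too small. It was 0.67 for fatty acid oxidation, 0.27 for heat shock, 0.24 for ribosomal proteins and 0.18 for the proteasome. The 4 positive medians were relative to the array median, and with no centring, which shifted every clone of a pool pair alike, they became -0.29 for ribosomal proteins, -0.26 for the proteasome, -0.30 for heat shock and -0.22 for xenobiotic enzymes.

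Fatty acid and triglyceride synthesis in liver on the second design had 4 of 9 genes positive and a median of -0.01, and its members past 0.05 adjusted over the list alone were Fasn and, at -0.34, Dgat2, which makes triglyceride. Fibroblast and matrix markers did not pass as a group (median -0.06, adjusted p 0.0910), while Mmp2 at -0.51 (SE 0.09) and the collagen gene Col1a1 at -0.41 (SE 0.08) were negative and Serpinh1, a collagen chaperone, was positive at 0.25, each past 0.05 adjusted over the list alone. Mmp2 is clone 20918, close in number to clone 20916 of Macir, also negative, and an effect of printing position was not tested for Mmp2. Past 0.05 adjusted over the list alone were all 3 of these matrix genes. The same held for Msmo1 in the cholesterol synthesis list of 3 measured genes (0.50 as a mean of its clones), for the interferon-induced gene Igtp at 0.27 and for the acute-phase gene Lcn2 at 0.42. None of these passed over all genes but Fasn. Red blood cell markers had a median of -0.02 over 5 genes, the neighbours of Sqle 0.00 over 23 and the citrate cycle 0.01 over 12, and none of the 3 passed.

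In liver on the first design most measured genes of the respiratory chain, the citrate cycle, fatty acid oxidation and the ribosome lay on the negative side, no gene passed, and these groups did not hold with an estimated correlation (adjusted p 0.651 for each). Among genes with 1 sign on all 4 arrays, Zfp281 had -1.09 (SE 0.25), Hdlbp, which encodes the RNA-binding protein vigilin, -0.87 (SE 0.19), Timm8b of the mitochondrial inner membrane import system -0.75, Alb, the serum albumin gene, -0.74 (SE 0.25) and Errfi1, a feedback inhibitor of the EGF receptor, -0.74. Gdap1 had -0.70, the retinol saturase gene Retsat -0.68, Tmed5 -0.67, Washc3 -0.63, Serbp1 -0.61, the fumarase gene Fh1 -0.60 and the proteasome gene Psma3 -0.54. Alb had -1.26 in pool pair 1 and -0.22 in pool pair 2. On the positive side were Etl4 at 0.76, Pmm1, the phosphomannomutase, at 0.71, Tanc2 at 0.71, the mannosyltransferase gene Alg3 at 0.67, Ptprz1 at 0.67, the endothelial cadherin gene Cdh5 at 0.64, Robo1 at 0.58, Snrpb2 at 0.56, B9d1 at 0.56, Commd9 at 0.55, Npr3 at 0.54 and the checkpoint kinase gene Chek2 at 0.51. Other clones of Ptprz1 (2 of 4), Etl4 (1 of 1), Tanc2 (1 of 2), Npr3 (1 of 1) and Snrpb2 (2 of 2) had the opposite sign. The 12 named clones of the positive side lay in 5 of the 48 printing blocks, where no random draw of 12 annotated clones lay in fewer than 7, and the 12 of the negative side in 7, which 10 of 10000 draws reached. Tanc2 had -0.62 on the second design. Sqle had -0.33 in pool pair 1 and 0.85 in pool pair 2, with a mean of 0.26 (SE 0.32).

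Of the 7680 liver clones on the first design 0 passed with limma, 253 had an unadjusted p under 0.05 (3.29%) and the smallest adjusted p was 1.0, and 0 of 3838 genes passed with clones averaged per gene. Clones with 1 sign on all 4 arrays numbered 633 (8.24%) where 4 independent arrays, which dye swaps of a pool pair are not, would give 12.5%, and 35 of these were past 1.5-fold. The pool pairs of liver had a correlation across clones of -0.20 on this design, and the lone other pool pair gave 42 calls without pool pair 1 and 140 without pool pair 2.

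The groups on the negative side in liver on the first design were the respiratory chain (17 of 18 genes negative, median -0.30, adjusted camera p 1.18e-06), ribosomal proteins (27 of 29, -0.26, 1.18e-06), the citrate cycle (12 of 13, -0.27, 6.56e-05), fatty acid oxidation (7 of 7, -0.19, 0.00226), heat shock (18 of 23, -0.12, 0.0132) and the proteasome (13 of 18, -0.11, 0.0364). None held with an estimated correlation, where the adjusted p was 0.779 for heat shock and the proteasome and 0.651 for the other 4. Their correlations were estimated at 0.44 for heat shock to 0.90 for the citrate cycle, above the preset 0.01. Examples were Ndufa10 at -0.53 and Atp5l at -0.52 of the respiratory chain, Rpl26 at -0.50 and Rpsa at -0.47 among ribosomal proteins, Fh1 and Sucla2 (-0.44) of the citrate cycle, and the acyl-CoA dehydrogenase genes Acadl at -0.74 and Acadm at -0.42. Markers of cell types lay on the same side: hepatocyte markers had 6 of 6 negative (median -0.28, adjusted p 0.00232), with Alb and Tdo2 at -0.43, and macrophage and immune markers 5 of 5 (median -0.26, 0.00783), with Lyz2 at -0.44 and Ctsb at -0.52. With an estimated correlation these cell-type lists had an adjusted p of 0.651 each. No member passed over all genes or adjusted over its list alone. All 8 calls were lost without pool pair 1, whose array with the Fob3b pool in green had a median of -0.82 over the genes of these lists where the other 3 liver arrays had -0.14, 0.08 and 0.00, and without that array 2 lists passed, 1 positive and 1 negative. Cholesterol synthesis (median 0.04), fatty acid synthesis (-0.02), glycolysis (-0.07) and the neighbours of Sqle (-0.02) did not pass in liver, and Cdh5 was the lone liver gene past 0.05 adjusted over its list alone, in the endothelial list of 3 genes.

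**Figure D3:**
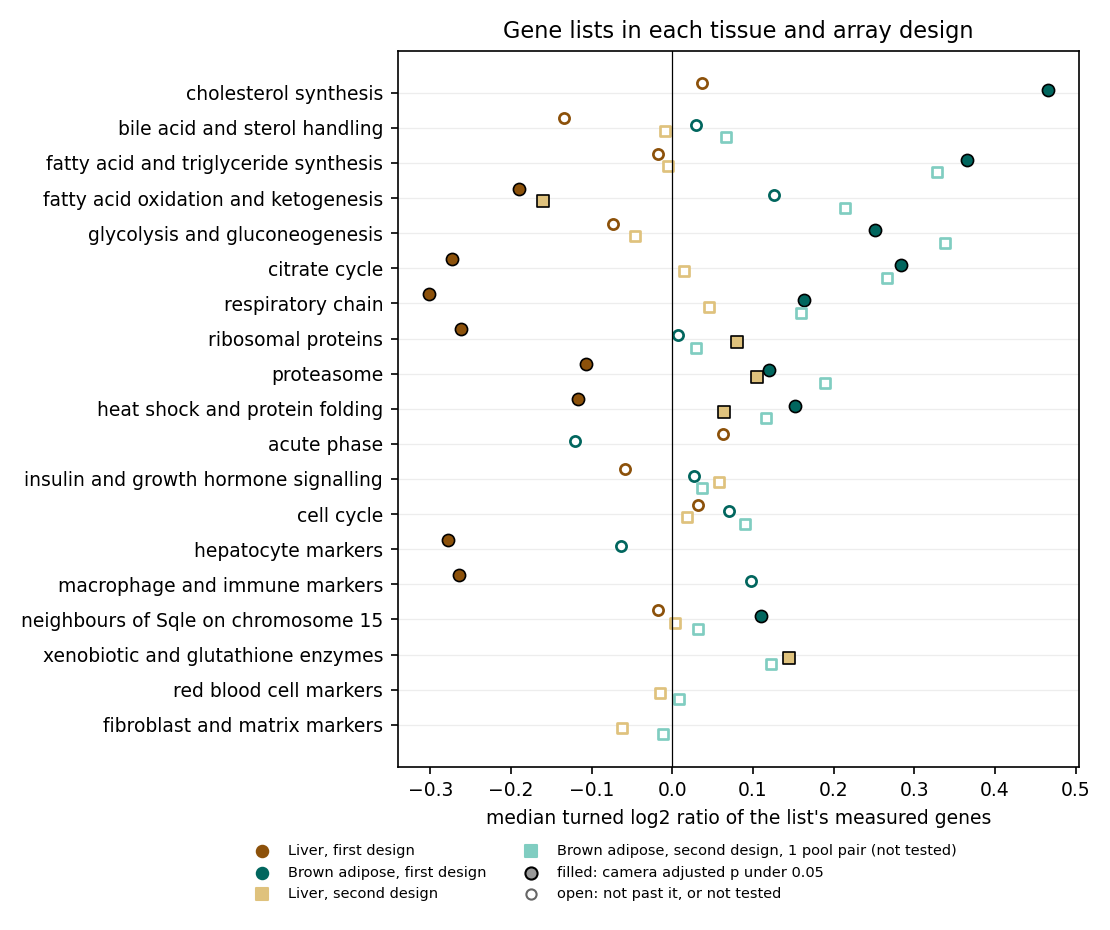
Median log2 ratio (x axis) of the measured genes of each list with at least 5 measured genes (y axis), with circles for the first array design, squares for the second, and filled markers where camera at its preset correlation gave an adjusted p under 0.05. The citrate cycle lies at -0.27 in liver and 0.28 in brown adipose tissue on the first design, and at 0.01 and 0.27 on the second.

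Whether the line effect differed between tissues was tested on the first design as liver minus brown adipose tissue. Me1 had the largest difference among genes with every liver array on 1 side and every brown adipose array on the other, at -1.17 (SE 0.34), with -0.41 in liver and 0.76 in brown adipose tissue. The peroxisomal beta-oxidation gene Hsd17b4 followed at -0.86, with -0.53 and 0.33, and Fbxo7 and Irak1 had -0.69 each. On the other side Tamm41, which acts in cardiolipin synthesis, had 0.80, with 0.46 in liver and -0.34 in brown adipose tissue, Cdca7 had 0.75 and Commd9 0.74. Other clones of Tamm41 (1 of 1) and Irak1 (1 of 1) had the opposite sign, and the other Me1 clone did not show the split, with 0.57 and 0.51 on the arrays of liver pool pair 2 and -0.22 on 1 brown adipose array. The 10 clones named on the positive side lay in 3 of the 48 printing blocks and the 7 on the negative side in 4, where 0 and 18 of 10000 random draws lay in as few. With each block centred their medians went from 0.49 to 0.25 and from -0.69 to -0.34. Sqle had -0.28 (SE 0.45).

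No gene passed this test of the difference. With limma 0 of 7680 clones had an adjusted p under 0.05, 220 had an unadjusted p under 0.05 (2.86%), and 28 had opposite signs in every array of the tissues (0.365%, where independent arrays, which these are not, would give 0.781%). By group 10 lists passed camera, all more negative in liver than in brown adipose tissue, led by the citrate cycle with 13 of 13 genes and a median difference of -0.52 (adjusted p 2.49e-08) and the respiratory chain with 18 of 18 and -0.49 (1.26e-07). None of the 10 held with an estimated correlation (adjusted p 0.514 for each). Scd2 at -1.25, in fatty acid and triglyceride synthesis, and Deptor at -1.37, in insulin and growth hormone signalling, passed when adjusted over the list alone, at 0.0362 and 0.0173. Macrophage and immune markers were among the 10, at a median of -0.36, and hepatocyte markers had -0.34 without passing (adjusted p 0.0937). Without liver pool pair 1, 0 lists passed camera, without its array with the Fob3b pool in green 4 did, and without the array of brown adipose pool pair 2 with Fob3b in red 0 did, where 6 did without both arrays of that pair.

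The liver results of the designs were compared over the 943 shared genes. Fasn had 0.06 on the first design and 0.63 on the second, Idh1 -0.45 and 0.23, and Me1 -0.25 and 0.03. Over all shared genes Pearson's r was -0.05, Spearman's rho was -0.04, and 49.0% had the same sign, with 0 genes past the threshold on both. These correlations are across genes of the same RNA pools and have no test.

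Arrays without a line difference gave the background. On the first design the F-line liver pool against itself had 13.2% of clones past 1.5-fold and the Fob3b-line pool 5.86%. The arrays of that design that compared the lines had 8.24% to 30.5%. Caln1, at -1.37 and -1.19, was among the genes farthest from 0 on both arrays of 1 pool against itself. On the second design pool 1 against pool 2 had 2.27% in the Fob3b line and 1.64% in the F line, beside 0.612% to 6.48% over its arrays that compared the lines. The crossed-pool arrays, whose dye-balanced mean estimates the same difference between lines as the direct arrays, had a Pearson r of 0.12 and a Spearman rho of 0.05 with them across clones, and 50.0% of all clones and 20 of the 29 called clones had the same sign. Clones are not independent replicates, so these carry no p.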

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

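The tests of printing position, crossed pools, Deptor, the single liver and brown adipose slides, the held priors, the second-design medians, the shared dye bias and the pattern shared with liver pool pair 2 were chosen after the results were seen; the test on the arrays of 1 pool against itself was chosen before its result. Among 37 groups of 4 arrays examined for a value apart from the rest, 1 stood out, which is no more than chance gives at about 1 in 20: Scd2 in brown adipose tissue had -0.29 on the array of pool pair 2 with the Fob3b pool in green, where the other 3 arrays had 1.57 to 1.88.

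In the test of the difference itself 10 gene groups passed camera at its preset correlation and 0 with an estimated correlation (adjusted p = 0.514 for each), and 0 passed without liver pool pair 1. Their median differences of liver minus brown adipose tissue were -0.24 for bile acid and sterol handling, -0.38 for fatty acid and triglyceride synthesis, -0.37 for fatty acid oxidation, -0.38 for glycolysis, -0.52 for the citrate cycle, -0.49 for the respiratory chain, -0.30 for ribosomal proteins, -0.27 for the proteasome, -0.28 for heat shock and -0.36 for macrophage and immune markers. For the genes that follow, every liver array went 1 way and every brown adipose array the other, and none passed the adjusted test of the difference. The log2 differences were 0.80 for Tamm41, 0.75 for Cdca7, 0.74 for Commd9, 0.56 for Rab23, 0.55 for Mydgf, 0.43 for Ext2, 0.39 for Fndc3c1, 0.39 for Kdm5a, 0.35 for Setd1b and 0.33 for Fhdc1. On the negative side they were -1.17 for Me1, -0.86 for Hsd17b4, -0.69 for Irak1, -0.69 for Fbxo7, -0.68 for Cir1, -0.64 for Tmco1 and -0.47 for Sec16a. Independent arrays would give such a split in 0.781% of clones, and 0.365% showed it, but dye swaps of a pool pair are not independent. The 10 clones of the positive side lay in 3 of the 48 printing blocks, where 10000 random draws gave at least 6, and the 7 of the negative side in 4, which 18 draws reached.

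On the first design 8 lists passed camera at its preset correlation on the negative side in liver and 8 on the positive side in brown adipose tissue, and 0 with an estimated correlation (adjusted p 0.604 to 0.779), with the citrate cycle (-0.27 and 0.28), the respiratory chain (-0.30 and 0.16), the proteasome (-0.11 and 0.12) and heat shock (-0.12 and 0.15) among both. A line difference in liver RNA is argued against for these 4 lists and ribosomal proteins, since their 5 medians on the second design, with the same RNA pools but 4 to 23 genes of a list shared, ran from 0.015 to 0.10, the interquartile range of each lying above 0.5 of its own first-design median, and the 46 shared genes had -0.28 on the first and 0.06 on the second design; it stays open for macrophage and hepatocyte markers, with 4 and 0 genes there, and for fatty acid oxidation, with -0.16 and 12 of 12 genes negative but a median of -0.0064 on the crossed-pool arrays. The liver side is in line with an effect of the slide of liver pool pair 1 with Fob3b in green, without which 1 of the 8 liver lists stayed past the threshold in the same direction (0 lists passed without both slides of that pair), while a dye bias tied to transcript abundance stays open: the test set beforehand, medians of the liver-list genes beyond 0.1 on both arrays of 1 liver pool against itself, came out for it with -0.24 and -0.15, but a bias shared by all slides is argued against by 0.82 as deposited on that slide (interquartile range 0.45 to 1.23) and cancels in a dye swap, which leaves a bias that differs between slides. In brown adipose tissue 1 slide of pool pair 2 was not the only source of the positive medians of 5 lists. In pool pair 1 alone cholesterol synthesis had 0.72, fatty acid synthesis 0.71, glycolysis 0.40, the citrate cycle 0.20 and the neighbours of Sqle 0.11. Whether their calls rest on 1 slide stays open. Without the slide of pool pair 2 with Fob3b in red 0 lists passed, although that leaves the pair in 1 dye orientation. The citrate cycle had 0.86 on that slide and -0.19 on the other slide of the pair. An effect of 1 slide also stays open for the respiratory chain, the proteasome and heat shock, with 0.072, 0.13 and 0.18 in pool pair 1. A difference in the RNA of brown adipose pool pair 1 is in line with second-design medians of 0.34 for glycolysis, where a pattern shared with the arrays of liver pool pair 2 is argued against by 0.023 there, and of 0.12 to 0.27 for the citrate cycle, the respiratory chain, the proteasome and heat shock, where it cannot be told apart from such a pattern (0.080 to 0.17 in liver pool pair 2, and 0.56 as the correlation across clones), while it stays open for fatty acid synthesis (0.33 against 0.71 on the first design), cholesterol synthesis (0.13 against 0.72, with 3 genes) and the neighbours of Sqle (0.031 against 0.11), and 1 pool pair does not separate a difference between the lines from one between these pools or in their handling.

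Deptor in brown adipose tissue is a hypothesis about a gene that neighbours Sqle, not a call. The lowest of the turned ratios of both clones on the 4 arrays was 0.27, for clone 11974, which argues against a dye effect as the whole of its ratios. Clone 773 was named for 1 sign on all arrays, so its sign could not test this. A smaller dye share stays open: in pool pair 2 the dye orientations gave 0.75 and 2.16 for clone 773 and 0.27 and 1.59 for clone 11974. Faulty spots are argued against by the lowest of the 16 spot values, 0.21. A sequence difference between the lines under the clones may still contribute, because both tissues share a genome: the liver minus brown adipose difference was -1.37 (SE 0.36, adjusted p 1.0), but liver gave 0.06 and 0.65 in its pool pairs, and its signal level is unknown. The 0.06 of pool pair 1 averages arrays of opposite sign, with 1.97 and -1.39 for clone 773 and 0.41 and -0.74 for clone 11974. That pair therefore gives no side, and the liver values cannot decide on a sequence difference. A difference in Deptor RNA between the lines remains open beside a sequence difference. With block centring the gene had 1.61 and with scaled arrays 1.72, with an adjusted p of 1.0 in both, and with no centring it had 2.0 with an adjusted p of 0.00333.

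The 29 liver clones past the threshold on the second design fit a printing effect for the most part. Of these 19 lay within 5 positions of another in the printing order, where the highest of 10000 random draws of 29 clones had 10. A line difference in the 27 clones of the negative side is argued against by their median of -0.019 on the crossed-pool arrays of the same 4 pools (interquartile range -0.15 to 0.04), against -0.59 on the direct arrays. Centring each printing block left their median at -0.51 with a median SE of 0.068 in place of 0.084 and ended the calls, while the prior degrees of freedom fell from 7.63 to 4.22: with these held at 7.63 all 29 clones passed (154 in all), and with the prior variance held as well 0 did. Fasn, on the positive side, kept 0.64 with block centring (SE 0.07, adjusted p 0.151) but had 0.56 and -0.33 on the crossed-pool arrays, so a line difference in Fasn stays open.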

How the results depend on the processing

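Block centring and leaving out 1 slide were tried only after the results were seen, and unless a reason is given the cause of a change was not tested. Of the named genes' ratios under the alternatives 456 kept their direction and side of the threshold, 18 passed it newly, 15 lost it and 7 turned (3 with no centring), and of the passing lists' medians 154 stayed, 122 lost the threshold and 15 turned (4 with no centring). In brown adipose tissue the count of 0 clones became 1 with no centring, 4 with the tissue fitted alone and 9 by the rule of 1 sign and 1.5-fold without a p, which sets no error rate. In first-design liver that rule gave 35, and for the difference between tissues 12. On the second design the 29 liver calls became 159 with no centring (27 of the 29 kept), 8 with every array as a replicate, 7 per gene, where fewer items are tested, and 0 with scaled spread, block centring, 4 RNA pools and crossed-pool arrays added. The robust prior gave 33. Without centring the median clone of a pool pair moved by -0.40 to 0.33 on the first design and -0.56 to -0.17 on the second. This shift, alike for every clone of a pool pair, took Setd1b to -0.011 and Fhdc1 to -0.032 in the difference and, in second-design liver, Esr1 to -0.0012, ribosomal proteins to -0.29, the proteasome to -0.26, heat shock to -0.30 and xenobiotic enzymes to -0.22. The lists past the threshold became 0 in all 4 comparisons with fry (smallest adjusted p 0.525) and with an estimated correlation (0.514). The test with an estimated correlation had 2 residual degrees of freedom on the first design and 1 on the second, so hardly any list could pass it. In the difference 6 of 10 passed with block centring.

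Leaving out a pool pair leaves a lone pair that is assumed to vary like the other tissue. The clone counts then ran from 42 to 140 in first-design liver, 0 to 1 in brown adipose tissue and 0 to 95 for the difference (13 without liver pool pair 1, 95 without 2). Lists past the threshold ran from 0 to 9 in liver, 6 to 8 in brown adipose tissue and 0 to 13 for the difference. Sqle ran from -0.068 to 1.16 in brown adipose tissue, -0.33 to 0.85 in liver and -0.90 to 0.33 in the difference. First-design liver medians ran from -0.56 to 0.021 for the citrate cycle, -0.45 to 0.033 for ribosomal proteins, -0.30 to 0.14 for the proteasome, -0.39 to 0.13 for heat shock and -0.68 to 0.14 for hepatocyte markers. On the second design a lone liver pair leaves no degrees of freedom and so values only, with heat shock from -0.0045 to 0.14. Without the liver pool pair 1 slide with Fob3b in green, 2 liver lists passed (1 positive, 1 negative) and 4 in the difference, with the proteasome at 0.075 and heat shock at 0.0065. Without the slide of brown adipose pool pair 2 with Fob3b in green 1 clone passed there, and without the one with Fob3b in red 0 lists passed in brown adipose tissue or in the difference, and the respiratory chain turned to -0.085, the proteasome to -0.058 and the neighbours of Sqle to -0.055. Leaving out 1 slide leaves a pool pair in 1 dye orientation, so that dye effects no longer cancel. Allowing 1 dye orientation changed nothing, since no values were missing. With no intensities, what signal over background limits could not be examined.

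The pool number as a block across tissues gave 0 clones for the difference (smallest adjusted p 0.739). Across clones the deviations of same-numbered liver and brown adipose pool pairs correlated at 0.38. The labels do not say that a number means the same animals in both tissues, so liver and brown adipose pool pairs share only a number.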

Other observations

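All values in this part were looked up after the main results were seen. Matrix genes in brown adipose pool pair 1 on the second design went both ways, with Serpinh1, a collagen chaperone, at 0.78, Sparc at 0.55, Col5a2 at 0.48, Mmp2 at -0.72 and Vim at -0.29, around a list median of -0.01. The glucose transporter gene Slc2a4 had 0.65, Pdhb and Dld of the pyruvate dehydrogenase complex 0.76 and 0.52, and the chaperone gene Hsp90aa1 0.68 in the same comparison. The neighbours of Sqle there included Slc45a4 at 0.55, Myc at 0.31 and Trib1 at -0.34. In first-design brown adipose tissue Npc2, which carries cholesterol out of lysosomes, had 0.52 (SE 0.19), while Npc2 had 0.36 in pool pair 1 on the second design, and neither passed or was tested over all genes.

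Pool 2 against pool 1 within a line, where a positive ratio means higher RNA in pool 2 if red was divided by green, gave the largest values of the between-pool arrays. Of the 10 genes farthest from 0 in the Fob3b line, 4 are among the 12 genes named on the positive side of second-design liver. The rest, such as Tmed3 at -1.58 and Bche at -1.55, are not. The 4 shared genes were A730082K24Rik at -1.73, Pip4p1 at -1.60, Paip2 at -1.49 and Mtfr1l at -1.42. On the crossed-pool arrays these 4 genes had 1.70, 1.62, 1.35 and 1.15 where Fob3b pool 1 was used and -0.58, -0.27, -0.26 and -0.34 where Fob3b pool 2 was used, and -0.24 to 0.17 between the F pools. Xenobiotic and glutathione enzymes had a median of -0.23 between the Fob3b pools and 0.05 between the F pools, and ribosomal proteins -0.02 and -0.13. Between the F pools Ddx42 had -1.67 and Ywhaq 1.02. Each of these is 1 array, without a test.

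Cell cycle genes had medians of 0.22 and 0.08 on the arrays of the F and the Fob3b liver pool against itself, where heat shock genes had -0.38 and -0.19. On the second design the ratios of brown adipose pool pair 1 correlated across clones at 0.56 with those of liver pool pair 2 and at 0.12 with those of liver pool pair 1.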
